A study of Mus musculus with 26 samples.

How the data were processed

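Messenger RNA of submandibular, sublingual, parotid, lacrimal and meibomian glands of male and female BALB/c mice was measured on 26 expression arrays. Per the labels, each array held RNA pooled from the glands of 5 animals (10 glands). There were 3 such pools per sex of the submandibular, lacrimal and meibomian glands, and 2 per sex of the sublingual and parotid glands. The age of the mice, the array platform, the labelling and the scanner were not given in the sources used here. The comparisons, the tests, the filter, the floor rule, the gene lists and the rule for naming genes were fixed before the data were examined.

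The deposited table held 1 linear intensity per probe and array, for 10500 probes. No processing notes came with it, so what the authors did to make these values was read from the values alone. They were scaled within each array, since the array medians over all probes lay between 0.928 and 0.955. They had a background subtracted, since small negative values occurred (lowest -0.699). A total of 2241 cells (0.821% of 273000, on 835 probes) held exactly -1, some of them on probes that were bright on all other arrays. No other value lay between -1 and the lowest of the others, so -1 was taken as a code for a missing spot and left out. The floor rule fixed in advance would have raised these cells to the floor. That version was run as an added alternative.

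The 1324 other negative cells and all smaller positive values were raised to a floor of 0.0234, the 1st percentile of the positive values. The values were then taken to log2. After the filter, 0.168% of the cells lay at the floor. The array medians over all probes spanned 0.0403 on the log2 scale, under the limit of 0.15 fixed in advance, so no further normalization was applied. A probe was kept if it reached the 30th percentile of its array on every array of at least 1 of the 10 groups of sex and gland. This left 8213 probes. A group is called dim for a probe if the probe lay below that percentile on every array of the group, and a fold against a dim group is given as a bound. A group is said to lie near the ceiling if it reached 80% of the maximum of its arrays. Array maxima ran from 103 in a meibomian pool to 868 in a lacrimal pool.

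On the array, 8983 probes had 1 gene symbol, 1 had several and 1516 had none. Symbols were checked against a RefSeq table of assembly GRCm38.p6, used for names only, and 8975 matched by Entrez identifier. Of the probes kept, 7262 had 1 symbol, for 7158 genes. What a probe reads was not tested beyond this annotation, so a symbol here stands for the probe that carries it.

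All 26 arrays were fitted together in limma 3.58.1 (R 4.3.3) with 10 group means and 1 shared estimate of the spread per probe. This fit had 16 residual degrees of freedom and 4.113 prior degrees of freedom. Males were compared with females in each gland and over the mean of the 5 glands. A moderated F test asked whether the sex difference differed between glands. Each gland was compared with the mean of the other 4, and the salivary glands with one another, with both sexes weighted equally. P-values were adjusted by Benjamini and Hochberg within each comparison at 0.05, and for gland comparisons the counts also require a log2 difference of at least 1. Errors are standard errors of the log2 difference, levels are geometric means of scaled intensity, and n counts pools. Calls shared by a pair of glands were compared with chance by the Fisher exact test. The number of arrays limits the precision: the median standard deviation between pools of the same group was 0.340 (submandibular), 0.349 (sublingual), 0.346 (parotid), 0.505 (lacrimal) and 0.242 (meibomian) on the log2 scale.

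Of 36 gene lists fixed in advance, 34 had at least 4 members among the probes kept and were tested. Tissue kallikreins and red blood cell markers had 2 and 3 and were not. The heat map of the report names the lists. Each list was tested with camera at the preset correlation of 0.01, and again with a correlation estimated from these arrays. Adjustment ran over 170 tests of sex and 170 of gland. The rotation test fry stood beside them and called 11 and 122. Members of a list that rose or fell are those past the adjusted p of the whole comparison, and a second count is adjusted over the list alone.

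Named genes are up to 12 per direction and gland for sex, and the 10 highest and 4 lowest for a gland, by log2 difference among the calls in which the arrays of the groups do not overlap. Up to 4 members per list, the Y-linked genes, Xist and the 10 genes of smallest F-test p also count as named.

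The pool letter is shared by the sexes, so male A was checked against female A and so on. Deviations from the group means were compared over 7555 probes without missing cells. In the glands with 3 pools per sex the 9 pairs of male and female arrays of the same letter had correlations of 0.441 to 0.816, and all 9 were the best of their gland. With 2 pools the centring leaves 1 value per gland, 0.650 in the sublingual and 0.518 in the parotid, of which only the sign bears on the pairing. The letters of the former glands mark something shared by the arrays of a pair, and the fit with a block per pair (8 residual degrees of freedom) stands beside a result where it changes the call or moves a count by more than 1.5 times. Across glands, arrays of the same sex and letter had correlations of -0.602 to 0.606, of which 24 of 46 lay below 0.

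The same deviations fell into 2 sets of arrays that no label records, along a component with 39.1% of their variance. Set 1 holds the 10 arrays of submandibular B, sublingual A, parotid A, lacrimal B and meibomian A of both sexes, and set 2 holds the other 16. The sets were seen only after the values arrived. Values within the sets stand beside the pooled ones. Set 1 has 1 pool per group, so an additive fit of sex and gland was used there, which gives the mean sex difference and the gland comparisons but no sex difference in a single gland. Of the sublingual and parotid glands set 2 has 1 pool per sex, whose spread is borrowed from the other groups.

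The fit was tested on simulated data with the means of the real arrays, a spread per probe pooled over the glands and a factor per gland. Of 100 probes seeded with a log2 difference of 2 between the sexes, 92% were recovered in the submandibular, lacrimal and meibomian glands, 79% in the sublingual and 77% in the parotid. For a difference of 1 the shares were 30%, 30%, 29%, 13% and 13% in the same order. False calls made up 11.6% of the calls in the lacrimal gland, 2.13% in the sublingual and 0% in the other glands. With the block they made up 32.4% in the lacrimal gland, 9.43% in the parotid, 6.88% in the sublingual, 6.18% in the submandibular and 0% in the meibomian. The F test recovered 52% and 1% of the differences of 2 and 1. A list of 20 genes shifted by 0.5, 1 of 50 lists in all, reached an adjusted p of 5.68e-08, and 0 of the others were called. A first version of this test drew the spread of each probe from too few arrays and was replaced. Differences between glands in the spread of single probes were not simulated, nor was correlation between the genes of a list. Deviations were drawn independently for each probe and list members at random. The list result therefore does not show how many false calls camera makes on lists of correlated genes.

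Other settings, also fixed in advance, were quantile, loess and median scaling, a filter at the 50th percentile and none, a floor at the 10th percentile, trended and robust priors, array weights, a block for the pool letter within glands, across glands and as a random effect, fits of the compared glands alone, thresholds of 0.01 and of other log2 differences, and leaving out each array. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.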

Results

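The arrays compared 5 exocrine glands of the head in male and female BALB/c mice. They covered the 3 major salivary glands, the lacrimal gland that makes the watery part of tears, and the meibomian gland that makes their lipid. A total of 8213 probes for 7158 genes entered the comparisons. Each value rests on 3 pools per sex in the submandibular, lacrimal and meibomian glands and on 2 in the sublingual and parotid glands. Differences are on the log2 scale, male minus female, with the standard error.

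Did the genes of the sex chromosomes mark the sex of the pools? Eif2s3y, a gene of the Y chromosome, lay between 1.21 and 10.7 in scaled intensity on all 13 male arrays and between 0.0234 and 0.230 on all 13 female arrays. It was at least 14.3-fold higher in male than in female submandibular glands (5.16 ± 0.56), at least 16.6-fold in the sublingual (5.90 ± 0.69) and at least 9.91-fold in the parotid (5.44 ± 0.69). In the lacrimal gland it was at least 6.99-fold higher (4.07 ± 0.56), and in the meibomian gland at least 21.7-fold (7.80 ± 0.56). Xist, the RNA that coats the inactive X chromosome of female cells, was at least 2.94-fold lower in males over the mean of the 5 glands (-3.90 ± 0.53). Uty, also Y-linked, was at least 2.70-fold higher in males over that mean (2.95 ± 0.31). The probes named for Kdm5d, Uba1y and Sry did not differ over the mean of the glands (-0.19 ± 0.24, -0.10 ± 0.17 and -0.03 ± 0.18, adjusted p = 1 for each).

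The adjusted p of the mean over glands was 4.63e-11 for Eif2s3y, 0.000212 for Xist and 1.14e-05 for Uty, and the F test found no difference between glands for Xist (adjusted p = 0.926). In single glands Xist passed in the submandibular alone (at least 3.10-fold lower in males, -4.92 ± 1.07, adjusted p = 0.0114, n = 3 pools per sex), and this call was lost without female submandibular B (-3.60, adjusted p = 0.0937) or male submandibular B (-4.75, adjusted p = 0.0573). In the meibomian gland Xist was at least 7.02-fold lower in males (-5.56 ± 1.07, adjusted p = 0.0915), a difference that passed without female submandibular B (adjusted p = 0.0154). Female pools of array set 1 held 1.91 to 6.19 of Xist and those of set 2 held 0.217 to 1.46, against 0.0234 to 0.351 in all males. With the block for pool pairs the lacrimal differences of Uty (at least 2.38-fold higher in males, 1.73 ± 0.63) and of the Kdm5d probe (-0.56 ± 0.48) passed at an adjusted p of 0.0496 and 0.0390, which they did not without it (0.143 and 0.698). The F test of Eif2s3y, Uty and the Kdm5d probe did not pass without the block (adjusted p = 0.0832, 0.0797 and 1) and did with it (0.0473, 0.0354 and 0.0332).

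**Figure D1:**
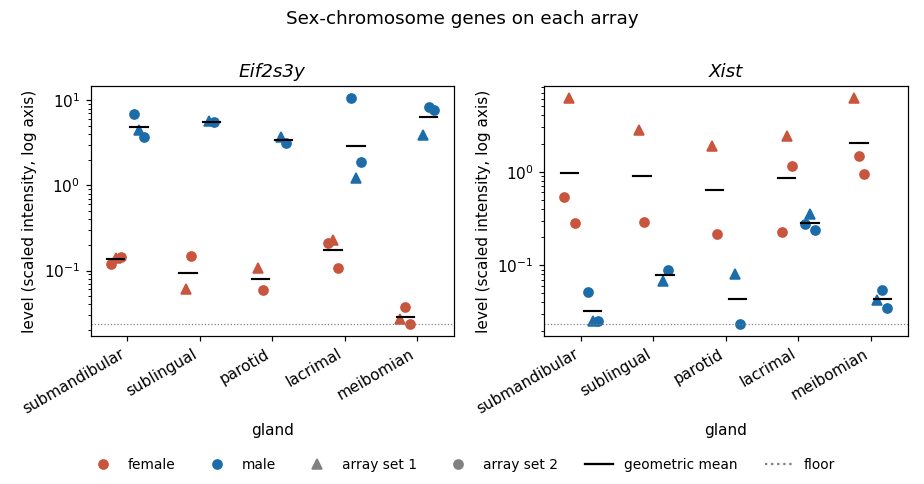
Level of Eif2s3y and Xist on each array (scaled intensity, log axis) by gland, females and males in different colours; triangles are array set 1, circles set 2, black bars the geometric mean of a group and the dotted line the floor. Eif2s3y parts the sexes in all glands, and Xist is highest in females of set 1.

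Over the 5 Y-linked probes the list rose in the meibomian gland, with a median of 0.38, a mean of 2.44 and an adjusted p of 1.30e-23 (4.46e-06 with an estimated correlation). It rose in the sublingual gland too, with a median of 0.57 and an adjusted p of 6.22e-05 (0.0150 with an estimated correlation). It also passed in the submandibular gland (median 0.04, adjusted p = 0.0233, but adjusted p = 0.164 with an estimated correlation) and in the parotid (median 0.35, adjusted p = 0.00747, but adjusted p = 0.0840 with an estimated correlation). Eif2s3y and Uty rose in the first 3 of these glands and Eif2s3y alone in the parotid, with the same members adjusted over the list alone. Each median is the value of a probe that did not differ over the mean of the glands. It was Kdm5d in the meibomian and parotid glands, Sry in the sublingual and Uba1y in the submandibular. The medians therefore do not measure a rise of Y-linked genes, and the calls rest on Eif2s3y and Uty. With the block for pool pairs the list was not called in the submandibular (adjusted p = 0.311), sublingual (0.0622) or parotid gland (0.0824), and in set 2 alone it was called in the meibomian gland only. Xist and the X genes that escape inactivation were lower in the male meibomian gland (median -0.42, adjusted p = 7.42e-10, and 0.000280 with an estimated correlation) and in the male parotid (median -0.54, adjusted p = 0.000761, and 0.0218 with an estimated correlation). In the submandibular gland the median was -0.60 (adjusted p = 0.00787, but adjusted p = 0.0632 with an estimated correlation). Of the 6 members 0, 0 and 1 fell in these glands, and 1, 1 and 3 adjusted over the list alone. In set 2 alone the parotid and submandibular shifts were not called (adjusted p = 0.0872 and 0.0508).

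How many genes differed between the sexes in each gland? The lacrimal and submandibular glands held most of the differences. In the lacrimal gland 444 probes were called, 238 higher and 206 lower in males, and in the submandibular gland 213, of which 158 were higher and 55 lower. With the block for pool pairs the shares shifted, to 510 higher and 600 lower in the lacrimal gland and to 334 and 259 in the submandibular. The sublingual gland had 17 calls (7 higher and 10 lower), the meibomian gland 3 and the parotid 2, all 5 of the latter higher in males. At an unadjusted p under 0.05 the numbers were 1210 (lacrimal), 826 (submandibular), 239 (sublingual), 133 (parotid) and 19 (meibomian). The sublingual, parotid and meibomian numbers lie below the share of 0.05 of the 8213 probes that chance alone would give. Few calls in these glands therefore do not show that the sexes are alike. With the block in the gland's own arrays the numbers were 770 (sublingual), 271 (parotid) and 563 (meibomian).

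With the block for pool pairs limma called 1110 probes in the lacrimal gland, 593 in the submandibular, 36 in the sublingual, 1 in the parotid and 3 in the meibomian. In array set 2 alone the calls were 330, 117, 3, 23 and 2 in the same order. When only the arrays of the gland itself entered the fit, limma called 93 in the lacrimal and 173 in the submandibular gland. The order of these glands was thus reversed, as it was with array weights (195 and 355). The fit of the gland's own arrays called 2 in the meibomian gland and 0 in the sublingual and parotid glands, where 159 and 79 probes had an unadjusted p under 0.05. Without male submandibular A, and likewise without male submandibular B, 141 probes were called in the submandibular gland. Without male sublingual A there were 29 in the sublingual gland, and without female parotid A, female parotid B or male parotid A there were 13, 6 or 8 in the parotid.

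**Figure D2:**
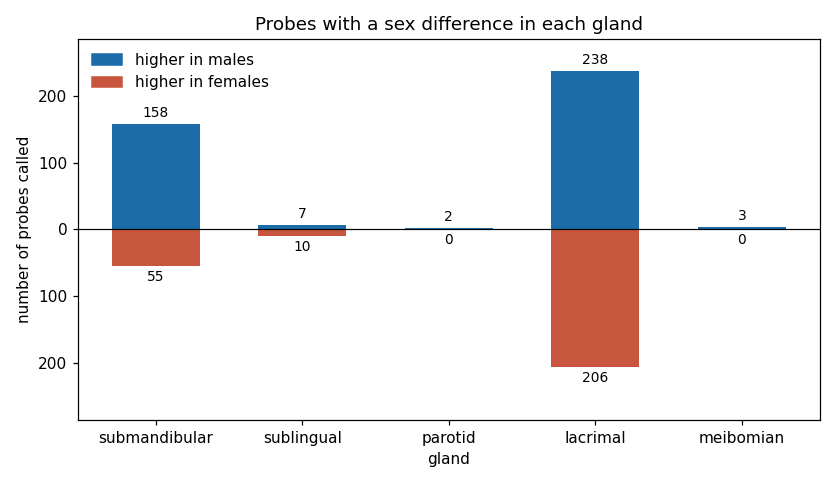
Number of probes called higher in males (upward bars) and higher in females (downward bars) at an adjusted p under 0.05, by gland. The lacrimal gland has 238 and 206, the submandibular 158 and 55. Fits of the gland's own arrays reversed the order of these glands.

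Which genes differed between male and female submandibular glands? The largest difference was in Sult1e1, which encodes the sulfotransferase that inactivates estrogens, at 102 in males and 0.362 in females (8.13 ± 0.59, n = 3 pools per sex). Products of the granular convoluted ducts, a part of the rodent gland that androgens enlarge, were among the largest: the kallikrein Klk1b24 at 190 against 6.14 (4.96 ± 0.46) and Egf at 207 against 14.5 (3.83 ± 0.50). Smr2, a submaxillary androgen-regulated protein, was at 76.3 against 3.11 (4.62 ± 0.40, 2 pools per sex measured), and the bicarbonate transporter Slc4a4 at 11.1 against 0.527 (4.39 ± 0.48). Cyp2b10 was at least 16.8-fold higher in males (4.78 ± 0.40), and the testosterone-forming enzyme gene Hsd17b3 at least 6.87-fold (4.68 ± 0.84). Higher in females were the sialyltransferases St3gal1 at 1.30 against 11.8 (-3.18 ± 0.48) and St3gal4 at 12.5 against 70.1 (-2.49 ± 0.39), the probe named for chymotrypsinogen, Ctrb1, at 2.26 against 14.2 (-2.65 ± 0.35), and the desaturase Scd1 at 8.69 against 38.0 (-2.13 ± 0.37).

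The adjusted p values were 7.82e-08 for Sult1e1, 8.80e-06 for Klk1b24, 6.48e-05 for Egf, 3.53e-05 for Smr2, 9.12e-06 for Slc4a4, 6.47e-07 for Cyp2b10 and 0.00201 for Hsd17b3. For the genes higher in females they were 0.000378 (St3gal1), 0.000595 (St3gal4), 7.94e-05 (Ctrb1) and 0.00128 (Scd1). In sets 1 and 2 the difference was 4.66 and 5.10 for Klk1b24, 3.36 and 4.06 for Egf, and -1.94 and -2.22 for Scd1. Hsd17b3 was not called in set 2 alone. With the missing code at the floor, the rule fixed in advance, Smr2 (3.08, adjusted p = 0.956) and St3gal4 (adjusted p = 0.270, at the same difference) were not called. Of the 213 calls 187 carried 1 gene symbol.

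Did gene lists shift between the sexes in the submandibular gland? Markers of smooth muscle and of the contractile myoepithelial cells that surround the secretory end pieces were higher in males (median 1.61). Of the 8 members 4 rose and 0 fell, and 6 rose adjusted over the list alone, among them Tagln at 14.6 against 4.35 (1.75 ± 0.27) and Actg2, at least 2.08-fold higher (2.25 ± 0.41). Skeletal muscle markers were also higher in males (median 0.92, adjusted p = 1.79e-07), but adjusted p = 0.356 with an estimated correlation. Of these 25 genes 7 rose and 0 fell, with 12 and 1 adjusted over the list alone, among them Pvalb, at least 10.1-fold higher (4.39 ± 0.75), and Tnnt3, at least 7.49-fold higher (3.31 ± 0.70). Collagen and fibroblast genes had a median of 0.47, of which 1 of 25 rose and 0 fell (2 and 0 adjusted over the list alone), with Postn higher by 1.32. That shift passed at an adjusted p of 0.000171, but adjusted p = 0.476 with an estimated correlation.

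The smooth muscle shift had an adjusted p of 1.46e-09, and 0.0010 with an estimated correlation. Ribosomal protein genes lay lower in males, with a median of -0.49 and 0 of 44 past the threshold on their own (0 adjusted over the list alone, adjusted p = 3.83e-06, but adjusted p = 0.775 with an estimated correlation). T cell markers had a median of -0.35 and 0 of 12 fell (1 adjusted over the list alone, adjusted p = 0.0439, but adjusted p = 0.748 with an estimated correlation), and with the block for pool pairs the T cell shift was not called (adjusted p = 0.169). The 4 growth factors of the granular ducts that were measured did not shift as a list (median 0.10, mean 0.87, adjusted p = 0.188).

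Which genes differed in the sublingual gland? A pair of granular duct genes that were higher in male submandibular glands were higher here as well: Klk1b24 at 33.9 in males and 1.80 in females (4.24 ± 0.57, n = 2 pools per sex) and Egf at 49.7 and 4.65 (3.42 ± 0.61). Sult1e1 was at least 27.0-fold higher in males (6.01 ± 0.72). The probe named for Mymk, a fusion factor of muscle precursors, was at 4.94 in males and 75.8 in females (-3.94 ± 0.59), and the clock gene Per1 at 1.26 and 4.53 (-1.85 ± 0.27).

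The adjusted p was 0.00167 for Klk1b24, 0.0106 for Egf, 0.000153 for Sult1e1, 0.00172 for Mymk and 0.00167 for Per1. In sets 1 and 2 the difference was 4.74 and 3.73 for Klk1b24 and 3.63 and 3.21 for Egf. Klk1b24 was not called with the missing code at the floor, the rule fixed in advance (adjusted p = 0.289, at the same difference). The Egf call was lost without female sublingual B (2.83, adjusted p = 0.218) or male sublingual A (2.62, adjusted p = 0.198). The Uty difference of 4.78 ± 0.77 (at least 3.93-fold higher, adjusted p = 0.00380) became 3.72 (adjusted p = 0.114) without female sublingual B. Without the block none of these calls was made from the 4 sublingual arrays alone, so in the main fit their error rests on the spread of the other glands. With the block for pool pairs the same 4 arrays gave 99 calls, and these genes were among them. In set 2 alone, with 1 pool per sex, only Mymk of these genes was called.

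**Figure D3:**
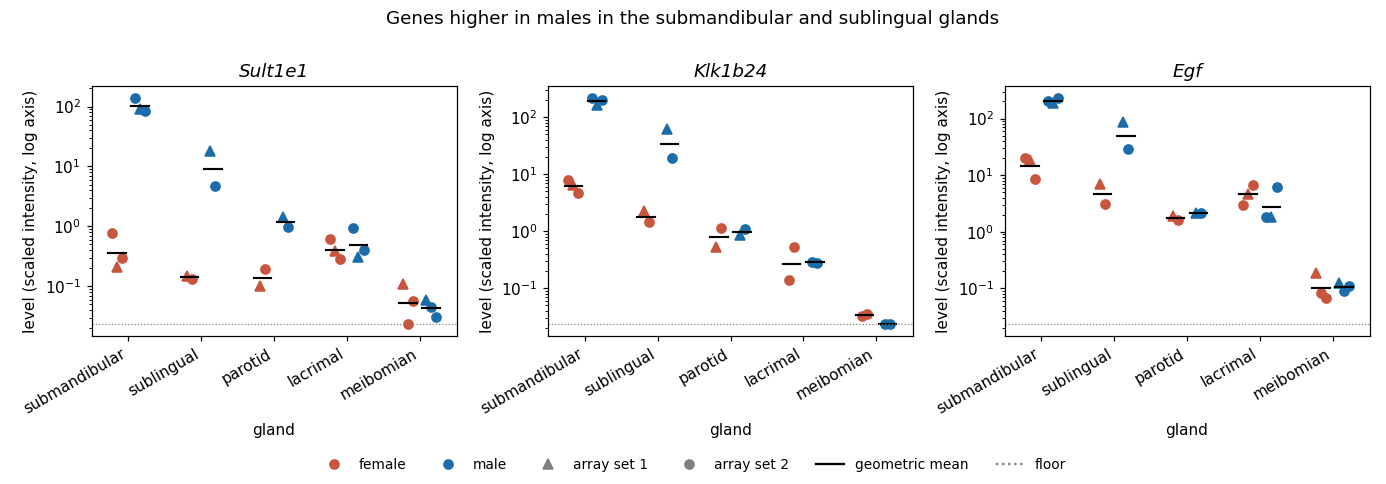
Level of Sult1e1, Klk1b24 and Egf on each array (scaled intensity, log axis) by gland, females and males in different colours; triangles are array set 1, circles set 2, black bars the geometric mean of a group and the dotted line the floor. In the submandibular gland Egf lies at 207 in males and 14.5 in females, in the sublingual at 49.7 and 4.65.

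The 4 measured growth factors of the granular ducts did not shift as a list in the sublingual gland (median -0.02, mean 0.79, adjusted p = 0.200). The list of sex steroid receptors and steroid metabolism rose in male sublingual glands (median 0.20, 1 of 20 rose, 1 adjusted over the list alone), with an adjusted p of 0.0228 but adjusted p = 0.545 with an estimated correlation. That shift was not called with the block for pool pairs (adjusted p = 0.0791), nor was it in set 2 alone (0.0872). Endothelial markers were lower in males (median -0.30, 0 of 12 fell, 0 adjusted over the list alone), at an adjusted p of 0.0211 but adjusted p = 0.389 with an estimated correlation. In set 2, with 1 pool per sex, their median was -0.55 (adjusted p = 0.00326), and skeletal muscle, T cell and MHC class II markers were lower in the male pool as well (medians -0.55, -0.60 and -0.34, adjusted p = 0.00262, 0.0180 and 0.0368). Nerve and Schwann cell markers had a median of -0.19 (0 of 8 fell, 1 adjusted over the list alone) at an adjusted p of 0.0371 but adjusted p = 0.316 with an estimated correlation. With the block the nerve shift was not called either (adjusted p = 0.0891), and in set 2 alone it had an adjusted p of 0.230.

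Which genes differed in the parotid gland? Of named genes only Eif2s3y was called, at least 9.91-fold higher in males (5.44 ± 0.69, n = 2 pools per sex, adjusted p = 0.000786). Sult1e1 was at least 3.45-fold higher in males without passing (3.10 ± 0.72, adjusted p = 0.690). Genes of fatty acid and wax ester synthesis were lower in males as a list (median -0.46), although 0 of 21 fell on their own and 0 adjusted over the list alone. Skeletal muscle markers were higher in males as a list (median 0.84, adjusted p = 9.08e-10), but adjusted p = 0.215 with an estimated correlation, and with a median of -0.08 in set 2 alone (adjusted p = 0.932). Of these 25 genes 0 passed the threshold and 0 adjusted over the list alone. Parotid tissue, averaged over the sexes, held more of these muscle transcripts than the mean of the other glands, a list shift not called with an estimated correlation.

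The lipid list had an adjusted p of 4.72e-07, and 0.0246 with an estimated correlation, with a median of -0.91 in set 2. In the same set, with 1 pool per sex, markers of other cell types moved beside it: adipocyte markers were lower in the male pool (median -1.15, adjusted p = 5.47e-05), and B and T cell markers were higher (medians 0.82 and 0.93, adjusted p = 0.000112 and 6.07e-06). Glutathione and xenobiotic genes had a median of 0.13 (0 of 35 past the threshold, 0 adjusted over the list alone, adjusted p = 0.0304, but adjusted p = 0.705 with an estimated correlation). Adipocyte markers had a median of -0.34 (0 of 11, and 0 adjusted over the list alone, adjusted p = 0.0304, but adjusted p = 0.636 with an estimated correlation). With the block for pool pairs neither was called (adjusted p = 0.0584 and 0.12). The second call of the parotid, a probe without a gene symbol, was at least 6.44-fold higher in males (5.92 ± 0.77, adjusted p = 0.000786) and was not called with the block (adjusted p = 0.0518).

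Which genes differed between male and female lacrimal glands? Ly6f was at 158 in males and 0.861 in females (7.52 ± 0.42, n = 3 pools per sex), Rsph6a at 193 and 2.26 (6.42 ± 0.36), and the fatty acid hydroxylase Cyp4a12a, an androgen-induced gene of the mouse kidney, at 215 and 2.96 (6.18 ± 0.56). The heparin-binding growth factor Mdk was at 148 and 3.63 (5.35 ± 0.44), and the fatty acid transporter Slc27a2 at 231 and 7.32 (4.98 ± 0.73). Higher in females were Asgr1, a lectin known from the liver, at 0.847 in males and 44.8 in females (-5.72 ± 0.34), the cysteine dioxygenase Cdo1 at 1.25 and 20.6 (-4.04 ± 0.26) and the alcohol dehydrogenase Adh1 at 18.3 and 195 (-3.42 ± 0.31). The lipase-related Pnliprp1 was at 3.72 in males and 520 in females (-7.13 ± 1.46).

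The adjusted p was 3.93e-10 for Ly6f and Rsph6a, 1.83e-07 for Cyp4a12a and Adh1, 5.73e-08 for Mdk, 0.000116 for Slc27a2, 7.24e-10 for Asgr1, 2.66e-09 for Cdo1 and 0.00397 for Pnliprp1. In sets 1 and 2 the difference was 7.75 and 7.40 for Ly6f, 6.09 and 6.58 for Rsph6a, -4.72 and -6.23 for Asgr1, and -3.07 and -9.15 for Pnliprp1. Of the 444 calls 391 carried 1 gene symbol. The lacrimal arrays varied more than those of the other glands, and from the 6 lacrimal arrays alone neither Pnliprp1 nor Eif2s3y was called.

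**Figure D4:**
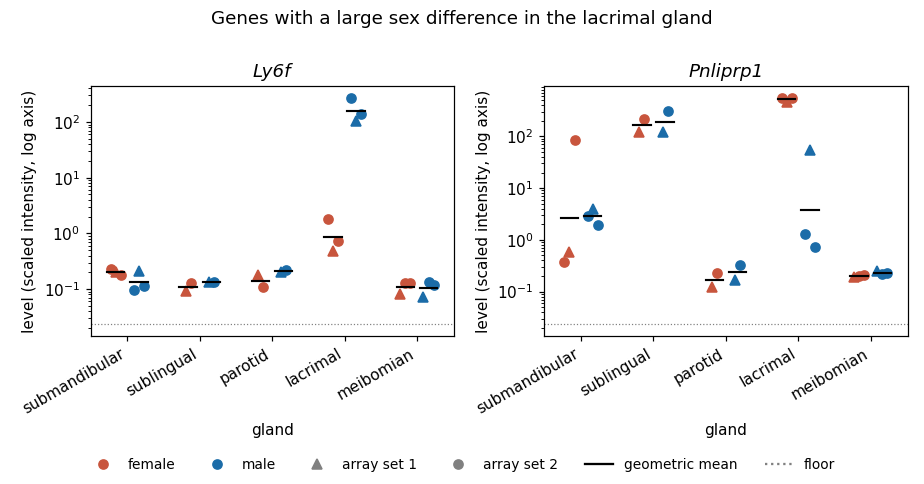
Level of Ly6f and Pnliprp1 on each array (scaled intensity, log axis) by gland, females and males in different colours; triangles are array set 1, circles set 2, black bars the geometric mean of a group and the dotted line the floor. In the lacrimal gland Ly6f lies at 158 in males and 0.861 in females, Pnliprp1 at 3.72 and 520.

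Did gene lists shift between the sexes in the lacrimal gland? Secreted carriers of small molecules, the lipocalins, secretoglobins and cysteine-rich secretory proteins, were higher in males (median 1.41, adjusted p = 0.00787), but adjusted p = 0.0632 with an estimated correlation. Of the 4 members 2 rose and 0 fell, and the same adjusted over the list alone: Crisp2 at 3.68 against 0.724 (2.35 ± 0.33) and Scgb3a1 at 2.02 against 0.441 (2.20 ± 0.41). Cell cycle genes were higher in males (median 1.09, adjusted p = 9.02e-10), but adjusted p = 0.389 with an estimated correlation, and their median was 0.34 in set 2. Of these 32 genes 2 rose, Cdc45 (3.22 ± 0.41) and Tyms (2.43 ± 0.37), and 7 adjusted over the list alone. Adipocyte markers were lower in males (median -1.04, adjusted p = 0.00621), but adjusted p = 0.476 with an estimated correlation, with 3 of 11 that fell, also adjusted over the list alone, among them Cebpa (-1.34 ± 0.28).

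In set 2 alone the adjusted p was 0.0532 for the carrier list, 0.0240 for the cell cycle list and 0.190 for the adipocyte list (median -0.87). With the block for pool pairs the fluid and electrolyte genes (median -0.32) and the ribosomal protein genes (median -0.24) were called lower in males (adjusted p = 0.0478 and 0.0174), which they were not without it (0.0590 and 0.168). An estimated correlation was not run with the block, which gave 32.4% false probe calls in the simulated lacrimal gland.

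Which genes differed in the meibomian gland? The 3 calls were 2 Y-linked genes and a probe without a gene symbol. Eif2s3y was at least 21.7-fold higher in males (7.80 ± 0.56, n = 3 pools per sex) and Uty at least 2.86-fold (4.08 ± 0.63). Genes of the interferon response were lower in males as a list (median -0.43), although 0 of 19 fell on their own and 0 adjusted over the list alone. By name, no gene of lipid synthesis was called in this lipid-secreting gland, which does not show that none differed.

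The adjusted p was 7.89e-08 for Eif2s3y and 0.00620 for Uty, whose call was lost without female meibomian C (3.53, adjusted p = 0.0997) or male meibomian A (4.01, adjusted p = 0.0574). The unnamed probe was at least 16.1-fold higher in males (7.40 ± 0.63, adjusted p = 6.69e-07). The interferon list had an adjusted p of 6.73e-16, and 0.0010 with an estimated correlation. It was not called in the other glands, but missed narrowly in the lacrimal (adjusted p = 0.0509, and 0.0368 in set 2 alone). With the block for pool pairs its median was -0.46 in the lacrimal gland, -0.38 in the submandibular, -0.22 in the parotid and 0.07 in the sublingual. The shift is thus not shown to be particular to the meibomian gland. The lipocalin and secretoglobin list (median 0.28, 0 of 4 rose, 0 adjusted over the list alone) passed at 0.0302, but adjusted p = 0.147 with an estimated correlation and 0.0824 with the block for pool pairs. The MHC class II list (median -0.14, 0 of 14 fell, 0 adjusted over the list alone) passed at 0.0115, but adjusted p = 0.476 with an estimated correlation. In set 2 alone these last lists had adjusted p values of 0.467 and 0.174.

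Did the sex difference itself vary between glands? The F test called 218 probes, and most of those with the smallest p were lacrimal genes. When the sex labels were drawn again within glands, 9 of 100 draws (the real one included) reached 218 calls. The 8 others among these parted the sublingual and parotid arrays by array set, as 12 draws did and the real labels did not. The highest of the 87 other draws was 122. Rsph6a differed by 6.42 ± 0.36 in the lacrimal gland and by -0.56 ± 0.36 in the submandibular. Ly6f differed by 7.52 ± 0.42 in the lacrimal gland and lay below the 30th percentile of the arrays in both sexes of the other 4. Trpm5, a channel of taste cells, was higher in males in the lacrimal gland (4.30 ± 0.32) and lower in males in the submandibular (-2.03 ± 0.32). Sult1e1 differed by 8.13 ± 0.59 in the submandibular gland and by 0.27 ± 0.59 in the lacrimal, and lay below that percentile in both sexes of the meibomian gland. Egf and Klk1b24 also varied between glands.

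The F test gave an adjusted p of 1.18e-07 for Rsph6a, 2.16e-07 for Ly6f, 3.36e-07 for Trpm5, 6.17e-06 for Sult1e1, 0.000784 for Egf and 0.000322 for Klk1b24. At an unadjusted p under 0.05 it had 732 probes, 136 passed in array set 2 alone and 580 with the block for pool pairs. Over the mean of the 5 glands 104 probes were called, 72 higher and 32 lower in males, with 653 at an unadjusted p under 0.05. Such a call can rest on a single gland: 73 of the 104 were called in 1 gland, 30 in more and 1 in none, and 82 passed the F test. Rsph6a passed for the mean (adjusted p = 0.00688) at 6.42 in the lacrimal and -1.46 in the sublingual gland. Of the 88 called probes with a symbol 1 parted all male from all female arrays. With the block 330 were called, 102 of the 104 among them, and in set 2 alone 47. In set 1, fitted additively with limma over 7972 probes and 4 residual degrees of freedom, 0 were called and 415 had an unadjusted p under 0.05.

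Did the glands share their sex differences? All 7 probes higher in male sublingual glands were also higher in male submandibular glands, where chance would give 0.135: Egf, Klk1b24, Sult1e1, Eif2s3y, Uty and 2 without a symbol. Of those higher in females 3 were shared, with 0.0670 expected, among them Per1. The submandibular and lacrimal glands shared 20 probes higher in males, with 4.58 expected, among them Mdk and St3gal5, and 9 higher in females, with 1.38 expected, among them Adh1 and Ctrb1. Of the 37 probes called in both of these glands 8 differed in opposite directions, among them Trpm5 and Opn1mw.

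By the Fisher exact test the adjusted p was 1.71e-11 and 8.25e-05 for the submandibular and sublingual glands (higher in males and in females), and 1.65e-07 and 2.20e-05 for the submandibular and lacrimal glands. The sublingual and lacrimal glands shared 2 probes higher in males (0.203 expected, adjusted p = 0.0266) and 0 higher in females (0.251 expected, adjusted p = 1). The 2 were Eif2s3y and a probe without a symbol that was higher in males in every gland, as a Y-linked gene would be. This overlap therefore bears on no other sex difference. Both probes are also among those shared by the submandibular gland with the sublingual and the lacrimal, and no test left them out. In all, 37 probes were called in the same direction in at least 2 glands, a count defined after the values were seen. It was 126 with the block for pool pairs and 16 in set 2 alone, and the probes of an array are not independent.

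What marked the submandibular gland against the other 4? The granular duct products Klk1b24 at 34.2 (6.16 ± 0.27, n = 6 pools) and Egf at 54.8 (4.91 ± 0.29) were among the genes higher here, as was tyrosine hydroxylase, Th, at 171 (5.51 ± 0.18). So were genes of salt transport across the striated ducts, such as Fxyd2 at 252 (3.41 ± 0.21), Atp1b1 (2.55 ± 0.12) and Scnn1b (2.65 ± 0.20). Klk1b24 and Egf were dim in the meibomian gland, which is part of the mean of the other 4, so the size of their differences is less certain. Their levels average unlike sexes, with Klk1b24 at 190 in males and 6.14 in females and Egf at 207 and 14.5. Male sublingual glands, at 33.9 for Klk1b24 and 49.7 for Egf, lay above female submandibular glands. The largest difference of all was that of the probe named for Mymk, at 211 (6.61 ± 0.28). Lactoferrin, Ltf, was lower than in the mean of the other glands (-4.64 ± 0.34), as was Cyp4a12a (-4.70 ± 0.32).

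In total 1009 probes were called, 467 higher and 542 lower, and 991 in set 2 alone. Fluid and electrolyte secretion genes were higher as a list (median 0.82, 12 of 21 rose and 2 fell, also adjusted over the list alone, adjusted p = 4.46e-05, and 0.0360 with an estimated correlation). Keratinised epithelium markers (median -1.13, 16 of 22 fell and 1 rose, 16 and 2 adjusted over the list alone, adjusted p = 2.86e-05) and hair markers (median -0.94, 6 of 13 fell, 9 adjusted over the list alone, adjusted p = 0.00142) were lower, each at 0.0475 with an estimated correlation. Oxidative phosphorylation genes were higher (median 0.45, 13 of 32 rose and 0 fell, 14 adjusted over the list alone) at an adjusted p of 2.86e-05, but adjusted p = 0.473 with an estimated correlation.

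What marked the sublingual gland? This gland secretes mucus, and Spdef, a regulator of mucous cells, was at 17.8 (2.79 ± 0.22, n = 4 pools). Markers of lymphocytes were higher here than in the mean of the other glands: Ighm at 12.7 (3.62 ± 0.34), Ms4a1 at 5.36 (4.72 ± 0.58), Cd3d at 5.14 (2.82 ± 0.28) and the B cell attractant Cxcl13 (3.47 ± 0.41). The glial filament gene Gfap was at 64.4 (5.43 ± 0.50) and the potassium channel subunit gene Kcne1 at 7.25 (4.29 ± 0.23). Pnliprp1 was at 177 (6.88 ± 0.97), against a mean that includes the parotid and meibomian glands, where it was dim, so the size is less certain. Female lacrimal pools held more of it, at 451 to 558, so Pnliprp1 is not particular to the sublingual gland. Pigr, which carries antibodies into secretions, was at 42.9 (2.12 ± 0.42).

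In total 913 probes were called, 482 higher and 431 lower, and 835 in set 2 alone. B and plasma cell markers were higher as a list (median 1.68, 10 of 15 rose and 1 fell, 11 and 1 adjusted over the list alone, adjusted p = 6.36e-07, and 0.0475 with an estimated correlation). MHC class II genes were higher too (median 0.99, 11 of 14 rose and 0 fell, 12 adjusted over the list alone, adjusted p = 6.36e-07, and 0.0475 with an estimated correlation), and so were glandular defence proteins (median 1.10, 7 of 9 rose and 0 fell, also adjusted over the list alone, adjusted p = 0.000355, and 0.0360 with an estimated correlation). T cell markers were higher (median 1.89, 10 of 12 rose and 0 fell, 11 and 1 adjusted over the list alone, adjusted p = 7.86e-08), but adjusted p = 0.0694 with an estimated correlation. Skeletal muscle markers were lower (median -2.38, 19 of 25 fell and 0 rose, also adjusted over the list alone, adjusted p = 1.08e-12), but adjusted p = 0.0669 with an estimated correlation. Their array medians were -2.32 to -1.27 here and -1.87 to -0.79 in the lacrimal gland, against 1.49 to 3.18 in the parotid. The fall is thus not particular to the sublingual gland. Lymph nodes lie beside this gland, and which cells gave the lymphocyte transcripts cannot be read from pooled tissue.

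What marked the parotid gland? The serous parotid is the main source of salivary amylase, and Amy1 was at 280 (3.11 ± 0.63, n = 4 pools). The probe named for Cdx2 was at 43.5 (5.59 ± 0.25), Chil3 at 181 (5.52 ± 0.61) and Creb3l1, a regulator of secretory cells, at 72.3 (3.91 ± 0.29). Lactoperoxidase, Lpo, was at 197 (2.43 ± 0.19). This lay below its level in the lacrimal gland, and the mean of the other glands includes the meibomian gland, where Lpo was far lower. The secretoglobin Scgb1b2 (-5.82 ± 0.26) and Agr2, a protein of mucous cells (-5.56 ± 0.20), were lower. The tissue also carried more transcripts of fat and muscle, such as Adipoq at 42.7 (2.54 ± 0.30), Car3 at 42.2 (2.65 ± 0.36) and Tnnc2 at 43.4 (5.15 ± 0.67).

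In total 1402 probes were called, 735 higher and 667 lower, and 1292 in set 2 alone. Skeletal muscle markers were higher as a list (median 2.20, 19 of 25 rose and 0 fell, 20 adjusted over the list alone, adjusted p = 1.43e-12), but adjusted p = 0.0669 with an estimated correlation. Adipocyte markers were higher (median 2.05, all 11 rose, also adjusted over the list alone, adjusted p = 6.38e-07), but adjusted p = 0.0694 with an estimated correlation. Cholesterol synthesis genes were lower (median -1.20, 10 of 13 fell and 1 rose, 11 and 1 adjusted over the list alone, adjusted p = 0.00115), but adjusted p = 0.184 with an estimated correlation. No list of this gland passed with an estimated correlation.

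What marked the lacrimal gland? Sval2 was at 510 (9.46 ± 0.25, n = 6 pools), and the casein gene Csn1s2a was at 132 (7.45 ± 0.24) and haptoglobin, Hp, at 262 (6.92 ± 0.21). Lactoperoxidase, Lpo, was at 454 (3.94 ± 0.16) and lactoferrin, Ltf, at 56.7 (5.44 ± 0.34), although the list of glandular defence proteins did not shift (median 0.02, 3 of 9 rose and 3 fell, adjusted p = 0.665). The water channel gene Aqp8 was at 45.9 (8.45 ± 0.26). The secretoglobin Scgb1b2 was at 650, near the ceiling of its arrays (4.64 ± 0.23). Pump subunit genes of the salivary ducts were lower, such as Atp1b1 (-4.20 ± 0.12) and Fxyd2 (-4.56 ± 0.21).

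In total 1659 probes were called, 955 higher and 704 lower, and 1874 in set 2 alone. Quantile scaling turned this split into 717 higher and 1127 lower, or 38.9% higher in place of 57.6%, and moved the median of all probes from 0.12 to -0.06. Fluid and electrolyte secretion genes were lower as a list (median -1.36, 12 of 21 fell and 4 rose, also adjusted over the list alone, adjusted p = 8.94e-05, and 0.0360 with an estimated correlation), as were nerve markers (median -0.90, 6 of 8 fell and 0 rose, also adjusted over the list alone, adjusted p = 0.000205, and 0.0360 with an estimated correlation). Genes of the secretory pathway were higher (median 1.05, 23 of 30 rose and 2 fell, 24 and 2 adjusted over the list alone, adjusted p = 9.21e-06), among them P4hb at 191 (1.88 ± 0.18), but adjusted p = 0.0796 with an estimated correlation. Ribosomal protein genes were higher (median 0.66, 32 of 44 rose and 0 fell, 33 adjusted over the list alone, adjusted p = 0.000200), but adjusted p = 0.554 with an estimated correlation, and under quantile scaling their median was -0.09.

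What marked the meibomian gland? Enzymes that make very long and wax ester lipids were higher than in the other glands: Elovl4 at 126, near the ceiling of its arrays and at least 320-fold higher (8.92 ± 0.31, n = 6 pools), Elovl3 at 102, at least 232-fold higher (8.01 ± 0.20), and Scd3 at 41.3, at least 112-fold higher (7.79 ± 0.22). Cholesterol synthesis followed, with Cyp51 at 60.6 (5.62 ± 0.19) and Msmo1 at 104 (4.98 ± 0.19). The tissue also carried keratinised epithelium, with Sprr1a at 108, at least 289-fold higher (9.43 ± 0.37), and Krt13 at 32.4 (8.30 ± 0.45). The hair keratin gene Krt27 (at least 14.4-fold, 5.05 ± 0.25), the pigment cell gene Dct (4.58 ± 0.22), the muscle gene Tnnc2 at 78.9 (6.02 ± 0.49) and Top2a, a gene of cell division (3.20 ± 0.34), were higher as well. Lpo (-9.29 ± 0.16) and Amy1 (-8.33 ± 0.54) were lower.

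In total 3112 probes were called, 1394 higher and 1718 lower, and 3255 in set 2 alone. Quantile scaling turned this split into 1433 higher and 1378 lower, or 51.0% higher in place of 44.8%. Of 21 genes of fatty acid and wax ester synthesis 18 rose and 3 fell (also adjusted over the list alone, median 2.92, adjusted p = 3.22e-07, and 0.0360 with an estimated correlation). Keratinised epithelium markers (median 4.72, 20 of 22 rose and 1 fell, also adjusted over the list alone) passed at 5.02e-10, and at 0.0252 with an estimated correlation, and hair markers (median 2.32, 9 of 13 rose and 1 fell, also adjusted over the list alone) at 0.000294 and 0.0360. Cholesterol genes (median 2.63, 12 of 13 rose and 1 fell, also adjusted over the list alone) passed at 7.98e-06, but adjusted p = 0.0708 with an estimated correlation. Skeletal muscle markers (median 2.91, 23 of 25 rose and 1 fell, also adjusted over the list alone) passed at 7.86e-08, but adjusted p = 0.139 with an estimated correlation. Cell cycle genes (median 0.98, 25 of 32 rose and 2 fell, also adjusted over the list alone) passed at 0.00115, but adjusted p = 0.495 with an estimated correlation. Melanocyte markers (median 2.18, 4 of 5 rose and 0 fell, also adjusted over the list alone) passed at 0.0383, but adjusted p = 0.126 with an estimated correlation. Skin, hair and muscle lie in the eyelid around the gland, so these lists describe the dissected tissue.

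**Figure D5:**
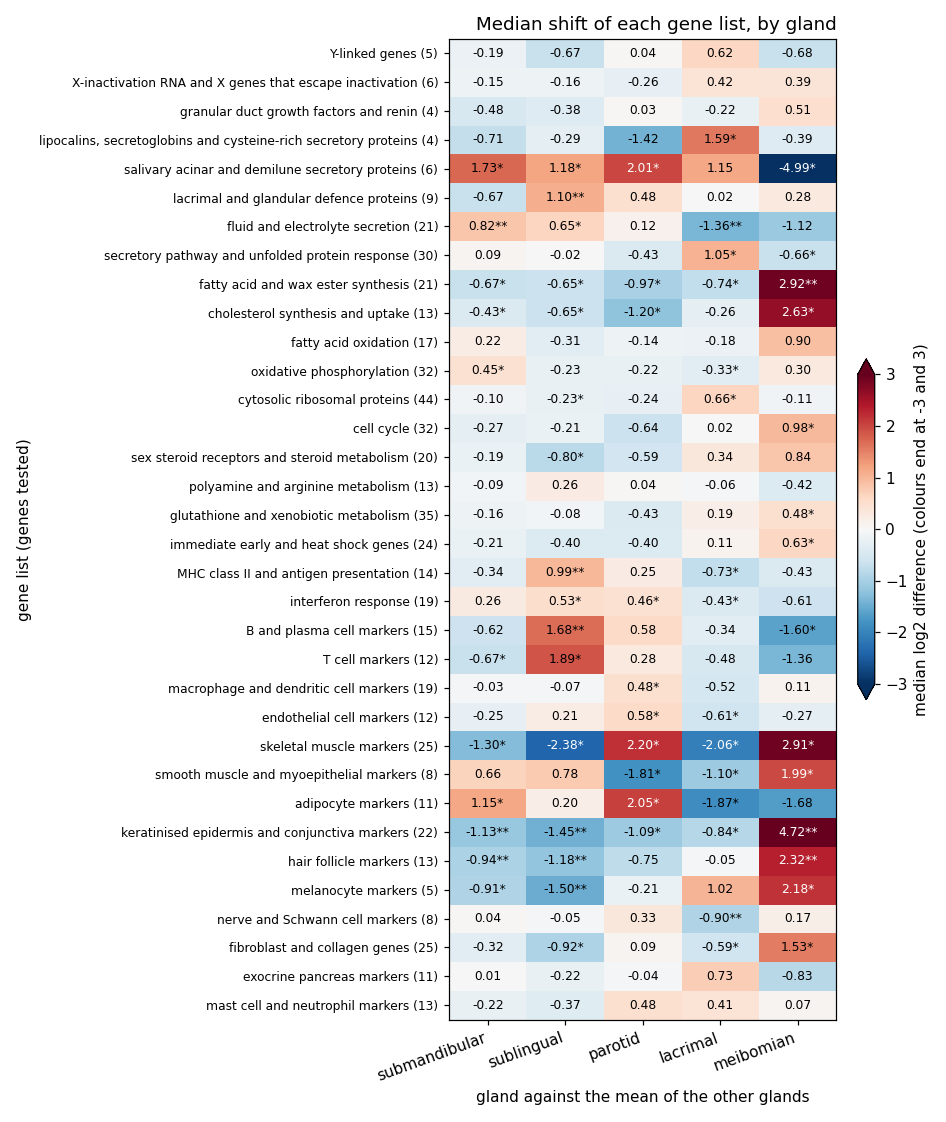
Median log2 difference of 34 gene lists (rows) in each gland against the mean of the other 4 (columns), with colours that end at -3 and 3; 1 star marks an adjusted p under 0.05 and a double star the same with an estimated correlation. Keratinised epithelium (4.72) and lipid synthesis (2.92) stand out in the meibomian gland, skeletal muscle in the meibomian (2.91) and parotid glands (2.20).

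How did the 3 salivary glands differ from one another? Against the sublingual gland the submandibular had more of the probes named for Mymk (3.45 ± 0.38) and Smap1 (3.90 ± 0.48) and less Pnliprp1 (-6.03 ± 1.15, n = 6 and 4 pools). Against the parotid it had more Scgb1b2 (7.40 ± 0.31) and Mymk (7.80 ± 0.38), and less of the probe named for Cdx2 (-5.35 ± 0.30) and of the calcium pump gene of fast muscle, Atp2a1 (-5.13 ± 0.53). Pnliprp1 was at least 510-fold higher in the sublingual than in the parotid gland (9.80 ± 1.26, n = 4 pools each), which had more of the muscle genes Tnnc2 (-7.94 ± 0.81) and, at least 59.3-fold, Pvalb (-7.82 ± 0.65).

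Between the submandibular and sublingual glands 850 probes were called, 381 higher and 469 lower in the submandibular, and 807 in set 2 alone. Between the submandibular and parotid glands there were 1379, 619 higher and 760 lower, and 1258 in set 2. Between the sublingual and parotid glands there were 1129, 444 higher and 685 lower in the sublingual, and 866 in set 2.

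Over all lists, 25 of 170 tests of sex passed, 13 upward and 12 downward in males, and 7 with an estimated correlation, with 49 at an unadjusted p under 0.05. Of 170 tests of gland 66 passed, 31 higher and 35 lower, and 14 with an estimated correlation, with 79 at an unadjusted p under 0.05.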

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

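The pattern weighed here was picked out after the results were seen. Of its tests, the comparison with submandibular genes and the rescaling were written before their values were computed, and the spread required of the first was added after its value was seen. A result is listed because an F test showed that the sex difference differed between glands.

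The sex difference varied between glands for 218 probes. The smallest adjusted p values of the F test were 1.18e-07 (Rsph6a), 2.16e-07 (Ly6f), 3.36e-07 (Trpm5), 3.55e-07 (Asgr1), 4.03e-06 (Cdo1), 5.70e-06 (Twist2), 6.17e-06 (Mtx1), 6.17e-06 (Sult1e1), 1.10e-05 (Olfr140) and 1.57e-05 (Chst2). Of the 54 genes named among the largest sex differences 40 passed this test. Among those that did not were Eif2s3y (adjusted p = 0.0832), Uty (0.0797) and Xist (0.926), as well as Pnliprp1 (0.148), which is therefore not shown to be confined to the lacrimal gland. Fitted with the block for pool pairs, Eif2s3y (0.0473) and Uty (0.0354) passed, as did Hsd17b3 (0.000219, without the block 0.0508), Tmigd1 (0.0273, 0.0734), Slc25a37 (0.00459, 0.0611), Zfp467 (0.0242, 0.0582) and Abcb1a (0.0446, 0.139). Twist2 differed by 3.70 ± 0.33, Mtx1 by 3.75 ± 0.27 and Chst2 by 3.94 ± 0.30 in the lacrimal gland. When the sex labels were drawn again within each gland, 9 of 100 draws, the real labels included, called at least 218 probes in the F test, and the highest other draw called 562. These draws ignore the array sets and the pool pairs, and by them chance can not be excluded for this count as a whole. Of the 8 other draws that reached it all parted the sublingual and parotid arrays by array set, and of the 87 draws that did not the highest called 122, a comparison made after the values were seen. The array sets are thus a structure that can raise the count of a draw. With the real labels set 1 held both sexes of every gland, so the sets do not part the sexes there. Of 8 other draws of which this also holds 0 reached 218 (median 0.5), which are too few to exclude chance. Of the 8 draws that reached 218, 4 also kept the real grouping of the lacrimal or submandibular arrays, so such draws are not free of sex differences. When only the labels within pool pairs were swapped, 6 of 100 draws reached it and the highest other called 315. The 5 others all kept the real grouping of the lacrimal and of the submandibular arrays, so these 5 do not bear on chance. The highest of the 71 swaps that did not keep the lacrimal grouping called 62.

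A pair of granular duct genes were higher in male than in female sublingual glands, Egf by 3.42 ± 0.61 and Klk1b24 by 4.24 ± 0.57 (n = 2 pools per sex), while the list of 4 granular duct growth factors did not shift (adjusted p = 0.200). Submandibular tissue in the sublingual pools might give this, since the glands touch. Over 17 probes bright in the female submandibular gland and at least 4 log2 units lower in the female parotid, lacrimal and meibomian glands, the median of the male sublingual minus the male submandibular level was -2.85 (quartiles -3.38 and -2.55), against -2.06 for Egf, -2.49 for Klk1b24 and -3.47 for Sult1e1. Egf and Klk1b24 lay above 13 of these probes and below 3, and both met the bound written in advance, yet Klk1b24 passed the upper quartile by less than the standard error of 0.559. In females the median of the set was -1.58, near Egf (-1.64) and Klk1b24 (-1.77), and its members Mymk, Zfp467, Arid1a and a probe without a symbol were themselves called lower in male sublingual glands, so tissue carried over and expression in the sublingual gland cannot be told apart. A shift of all probes in the sublingual males is not a likely cause, as the median sex difference over the probes kept was 0.04 in this gland. The Egf difference was 3.54 ± 0.67 (adjusted p = 0.0215) after quantile scaling. With medians so close, that scaling could hardly have removed it, so this value adds little.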

How the results depend on the processing

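Directions held for the named sex differences that passed the threshold in either fit. Outside the leave-one-out fits 2243 values kept their label, 232 were weaker, 8 stronger and 0 reversed. A change of sign where both values missed the threshold counts as a kept label, so the directions of such values are not shown to hold. Of 64 largest sex differences 34 were called in every setting. For genes of the gland comparisons 9551 were kept, 204 weaker and 13 reversed, and for lists 285, 102 and 2. The block for pool pairs ended the call of Jchain in the lacrimal gland (2.89, adjusted p = 0.0314 without and 0.0656 with it) and made that of the X-linked list in the sublingual gland (-0.27, 0.107 and 0.0448). Among the largest sex differences and the lists given in the report it changed no other call, apart from those given beside the results and the F tests of 8 genes. The cause of a change was not tested unless stated. The fits with the missing code at the floor, with the array sets and with the block in the gland's own arrays were added after the data were seen. Signal over background limits what dim probes can show, so a fold against a dim group stays a bound.

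Sex counts moved as follows. At an adjusted p under 0.01 the submandibular gland had 123 calls, the lacrimal 246, the mean over glands 54 and the F test 136. With a log2 difference of at least 1 the mean had 33. Array weights gave 355 (submandibular), 195 (lacrimal) and 5 (meibomian). The block for pool pairs gave 593 (submandibular), 36 (sublingual), 1 (parotid), 1110 (lacrimal), 330 (mean), 580 (F test) and 126 shared between glands, and within the gland's own arrays 412, 99, 0 and 121 for the first 4. Without the block the own arrays gave 0 (sublingual), 0 (parotid) and 93 (lacrimal). The array set as a block gave 170 for the mean and 65 shared. Set 2 alone gave 117 (submandibular), 3 (sublingual), 23 (parotid), 47 (mean), 136 (F test) and 16 shared, and set 1 alone 0 for the mean. Leaving out 1 array gave 141 to 277 in the submandibular gland, 13 to 29 in the sublingual, 2 to 13 in the parotid, 342 to 483 in the lacrimal, 2 to 4 in the meibomian, 82 to 141 for the mean, 185 to 263 for the F test and 26 to 47 shared.

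Gland counts depend on the minimum difference. Without a minimum there were 2446 calls (submandibular), 1775 (sublingual), 2944 (parotid), 3973 (lacrimal), 5531 (meibomian), 1281 (submandibular against sublingual) and 2124 (submandibular against parotid). With a minimum of 2 there were 193, 250, 440, 421, 1061, 227 and 503 in that order, and 372 for sublingual against parotid. Without a filter the lacrimal gland had 2998, as dim probes entered. In set 1 alone the submandibular and sublingual glands differed in 387. Leaving out 1 array kept every gland count within 1.5 times. With an estimated correlation 21 of 91 list calls remained, 7 of 25 for sex and 14 of 66 for gland.

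Values labelled as reversed were all in gland comparisons. A list is labelled by the direction of its test and not by its median. In set 2 alone the medians of the skeletal muscle list in the parotid (-0.08) and of the Y-linked list in the submandibular gland (-0.02) were negative. As reported both were positive, and the label does not count this change. Under quantile scaling, in the lacrimal gland Rpl6 went from 1.03 to -0.043, Rpl35 from 0.92 to -0.086, Rpl10 from 0.90 to -0.078 and the ribosomal list from 0.66 to -0.091, and in the meibomian gland Rpl10 went from -0.96 to 0.059 and B2m from -0.65 to 0.17. With the missing code at the floor, which by construction turns missing cells into very low ones, Cox5a went from 0.80 to -0.53 in the submandibular gland, and in the sublingual Klf4 from -1.10 to 0.49, Cnn1 from 2.07 to -0.68 and Tpsb2 from -0.93 to 3.27. The same setting moved Smr2 from 2.54 to -0.17 in the parotid, and Ndufc1 from -0.62 to 0.23, Rpl4 from 0.92 to -1.22 and Rpl10 from 0.90 to -1.36 in the lacrimal gland. It also ended the sex calls of Smr2, St3gal4 and Ttr in the submandibular and of Klk1b24 in the sublingual gland. In set 2 alone the ribosomal list of the sublingual gland went from -0.23 to 0.0023.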

Other observations

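The share of muscle markers higher in males, the tests of the Kdm5d probe, the swaps within pool pairs and the grouping of draws by array set were chosen only after the results were seen, and the other tests of this part were written before their values were computed.

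Pnliprp1, a gene known from the pancreas, was unevenly spread over the pools. It was at 84.6 in female submandibular pool C against 0.365 and 0.571 in the other female pools of that gland. In female lacrimal glands it lay between 451 and 558, and in males at 1.32, 0.725 and, in pool B of array set 1, 53.8. In the sublingual gland it lay between 119 and 315.

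A probe without a gene symbol was higher in males, as a gene of the Y chromosome would be: at least 7.68-fold in the submandibular gland (4.84 ± 0.63), 12.5-fold in the sublingual (5.78 ± 0.77), 6.44-fold in the parotid (5.92 ± 0.77, not called with the block for pool pairs, adjusted p = 0.0518), 3.65-fold in the lacrimal (2.55 ± 0.63) and 16.1-fold in the meibomian (7.40 ± 0.63), with 5.30 ± 0.31 over the mean of the glands (adjusted p = 6.33e-10). Another probe without a symbol was higher in male sublingual glands by 3.59 ± 0.34 (adjusted p = 7.49e-06). Their sequences were not given in the sources used here.

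Skeletal muscle markers were higher in male than in female submandibular glands, with array medians on the log2 scale of 0.39 to 0.61 in males and -1.51 to -1.18 in females. A single pool as the source is not likely: the median difference of 0.92 stayed between 0.71 and 0.96 when each array was left out. That 19 of the 25 markers (76%) were higher in males restates the difference, and its bound was set after the value was seen, so it does not bear on where the transcripts come from. Skeletal muscle in the dissected pools and a difference between the sexes in the gland itself both stay open.

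The probe named for Kdm5d, a Y-linked gene, gave signal in female glands, at 113 in female and 76.8 in male lacrimal glands. Male tissue in the female pools is not a likely cause, as the median over glands of the female minus male difference of Eif2s3y was -5.44. Females carry no Y chromosome, so with male tissue set aside the signal in females did not come from Kdm5d. That the probe lay above the 30th percentile on 13 of 13 female arrays restates the signal, and whether another transcript or something else on the spot gives it was not tested, since its sequence was not given.

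For single glands the arrays can be split into only 10 groupings of 3 against 3, which are too few to exclude chance. The real grouping called the most, 1 of 10, in the submandibular gland (213 against 1 for the highest other), the lacrimal gland (444 against 226, and against 1 among the 4 groupings that part all pool pairs) and the meibomian gland (3 against 0). With labels drawn again within each gland, 4 of 100 draws, the real one included, called at least the 104 probes of the mean over glands. This met the bound of a share under 0.05 set in advance, but lies too near it to exclude chance. Of the 3 others 2 kept the real grouping of the submandibular arrays, so such draws are not free of sex differences. The highest other draw called 412. It and the other draws that reached the real count, 3 in all, parted the sublingual and parotid arrays by array set, and the highest of the 87 draws that did not called 35. Swaps within pool pairs gave 1 of 100 and a highest other of 76. When gland labels were drawn again within each sex, only the real labels (1 of 100 draws) reached the real count in all 8 gland comparisons. Drawn labels move the differences between glands into the spread of a group, which made this outcome near certain. It shows that the glands differ, and says little about a single comparison. The highest other draws called 62 against 1009 (submandibular), 567 against 913 (sublingual), 1 against 1402 (parotid), 53 against 1659 (lacrimal) and 74 against 3112 (meibomian). For the salivary pairs they called 170 against 850, 0 against 1379 and 312 against 1129.

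No label records the array sets, the platform or the day of hybridisation. In the submandibular and lacrimal glands pool pairs shared more than their set: submandibular pools A and C both lie in set 2, yet male and female arrays of the same letter correlated at 0.537 and 0.477, against at most 0.0287 for different letters. For lacrimal pools A and C the values were 0.539 and 0.518 against at most -0.145. For meibomian pools B and C they were 0.533 and 0.597 against at most 0.491, which is a small margin.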
